A study of Mus musculus with 19 samples.

How the data were processed

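Gene expression was measured on Affymetrix mouse exon arrays in 19 samples of sorted bone marrow progenitors. The series design names the populations as common myeloid progenitors (CMP) and granulocyte-monocyte progenitors (GMP). Total RNA was purified with TRIzol, and 20 ng per sample was amplified with the WT-Ovation system and labelled with biotin, per the labels. The table deposited by the authors holds 1 intensity per exon-level probe set and array, on a linear scale from 1.34 to 16208. RMA, Partek and the mouse build mm9 are named per the submitters' processing notes, without a role or a version. How the 194293 deposited probe sets were chosen, and whether all 19 arrays were normalised in 1 step, is not given in the sources used here. Of the values on the other wild-type and Dnmt3a-/- arrays 22.2% to 23.0% also occurred on wild-type CMP replicate 1, and of those on the PR+/- arrays 22.0% to 22.8%, where 7.23% to 7.66% were shared by chance at the printed precision. That is expected if all 19 arrays were put on 1 common distribution, but does not show that they were run together. The array medians lay between 53.0 and 56.8 and the upper quartiles between 168 and 173, so the arrays were already on a common scale and were used as deposited.

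The log2 of each intensity was taken. Of the probe sets, 179496 carry 1 gene symbol, 1328 carry several and 13469 carry none in the probe annotation. The value of a gene on an array was the mean of the log2 values of the probe sets that carry its symbol alone, which gave 15781 genes with a median of 9 probe sets. Symbols were brought up to date through a reference gene table of assembly GRCm38.p6, used for names only: 13727 were found as annotated, 2039 were updated through a synonym and 37 were kept as annotated. No filter on dim genes was applied. The deposited table holds no measure of detection, so the median level of the germline list, 3.34, was taken as background after seeing the data. Where a group mean of a named gene lay under it, the change is given as a lower bound against that level ("at least"). That bound concerns background only: it is a point estimate, given without its sampling error. For arrays, their number limits the precision.

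The groups follow the labels. They comprise wild-type CMP (3 arrays), wild-type GMP (4), Dnmt3a-/- CMP (3), Dnmt3a-/- GMP (3), PR+/- GMP (2) and PR+/- Dnmt3a-/- GMP (4). PR is read as the PML-RARA fusion from the title of the series, since the labels do not spell it out. Replicates of the first 4 groups are numbered in the order of the numbers in their titles, and those of the PR+/- groups as in their labels. The labels do not state that the arrays of a group came from separate animals, so the p-values measure only the spread between these samples. Replicate numbers 1 and 2 occur in both PR+/- groups, but the labels do not say that they mark pairs, and the arrays that share a number were not clearly more alike across genes (r = 0.0774 and 0.0169), so no pairing was used. The title numbers of the Dnmt3a-/- arrays alternate CMP and GMP, and the labels do not say whether adjacent numbers mark 1 mouse. Deviations from the group means across genes correlated with r = 0.121, 0.139 and 0.171 for the 3 adjacent pairs and with -0.148 to 0.0305 for the others. Such pairs were therefore fitted as an alternative, with a shared random part (limma duplicateCorrelation, 0.181), while the comparisons themselves treat all arrays as separate.

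Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 15781 genes and a threshold of 0.05. Comparisons among the wild-type and Dnmt3a-/- CMP and GMP used 1 fit of 13 arrays. The comparison of PR+/- Dnmt3a-/- with PR+/- GMP used its 6 arrays. Comparisons of PR+/- with wild-type GMP, and of the Dnmt3a-/- effect between both backgrounds, used a fit of the 13 GMP arrays. The PR+/- arrays carry another style of label than the wild-type arrays, so a difference between array runs and the effect of PR+/- cannot be told apart.

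Gene lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison, where a list had at least 5 measured members. Camera with an estimated correlation and fry were run beside it, and the number of members past the threshold is also given adjusted over the list alone. The lists cover stem and multipotent progenitor, erythroid, megakaryocyte and platelet, basophil and mast cell, eosinophil, primary granule, secondary granule and neutrophil maturation, monocyte and macrophage, dendritic cell, B cell, and T and NK cell genes. Further lists cover cell cycle, p53 target, interferon-stimulated, immediate early and heat shock, ribosomal protein, mitochondrial respiration, retinoic acid pathway, imprinted and germline genes. Sort marker, myeloid transcription factor, DNA methylation machinery and sex-linked marker genes hold members of opposite roles and were counted but not tested as lists.

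The genes named in each comparison are Dnmt3a, genes among the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap, and genes among the 4 members of each list with the smallest p. For contrasts between effects and for the averaged effect the overlap condition was not used. Where fewer than 5 genes passed, the 5 with the smallest p in each direction were named as values. Predicted gene models, receptors of smell, small RNAs and Y-linked genes were left out of that rule. The lists, the rule, the tests and most of the alternatives were chosen before the data were examined.

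The alternatives were quantile normalisation, centring on array medians, the median or the brighter part of a gene's probe sets, removal of the dimmest 25% or 50% of genes, array weights, eBayes with trend and robust settings, a minimum change of 1.5-fold, only the groups compared, all 19 arrays in 1 fit, a replicate block in the PR+/- arrays, and leaving out each array in turn. Alternatives added after seeing the data left out 3 wild-type arrays or 2 PR+/- Dnmt3a-/- arrays of lowest correlation, used the title numbers of the wild-type arrays as a block, used the Y-linked signal of each array as a covariate or a filter, took adjacent Dnmt3a-/- title numbers as pairs, left out both arrays of such a pair, or left out each array in turn from the list tests of Dnmt3a-/- against wild type. The limma fit and camera were run on simulated data in which 200 of 15781 genes were changed with the same group sizes. Noise was drawn independently for each gene and array, with 1 spread per gene, so arrays that stand apart were not imitated. The fit recovered 62% of 2-fold and 97% of 4-fold changes in the CMP design, 66% and 99% in the GMP design, 24% and 77% in the design of 2 against 4 PR+/- arrays, and 37% and 91% for the difference between the effects in CMP and GMP. False calls made up 3.05% of the calls in the CMP design, the lowest share, and up to 7.78%, for the cell types in Dnmt3a-/-. Files were read with the R package data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.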

Results

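RNA levels were profiled on exon arrays in myeloid progenitors sorted from the bone marrow of mice. The labels give 3 arrays of wild-type CMP, 4 of wild-type GMP, 3 of Dnmt3a-/- CMP and 3 of Dnmt3a-/- GMP on the C57Bl/6J background. A further 2 arrays hold PR+/- GMP and 4 hold PR+/- Dnmt3a-/- GMP. Dnmt3a encodes a DNA methyltransferase that sets new methylation marks, and PML-RARA is the fusion protein of acute promyelocytic leukaemia. By its title, the series asks whether leukaemia driven by this fusion needs Dnmt3a. On the log2 scale the median gene had a mean level of 5.37, and the 5th and 95th percentiles of the gene means were 2.58 and 8.85.

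Arrays also differed within groups. Immediate early and heat shock genes, which respond to handling and stress, had a mean level of 8.61 in wild-type CMP replicate 1, and of 7.61 and 7.71 in wild-type GMP replicates 1 and 2. In PR+/- Dnmt3a-/- replicates 1 and 2 it was 8.54 and 8.47, and in the other 14 arrays it lay between 6.19 and 7.23. The same 5 arrays had the lowest mean correlations with the other arrays within their sets, and the 3 wild-type arrays among them are those of title numbers 21986 to 21988, apart from the other 4 (22003 to 22012). The Y-linked genes Eif2s3y and Kdm5d marked a second difference. Their mean level was at most 3.25 in all 6 Dnmt3a-/- arrays, 1 wild-type CMP, 1 wild-type GMP and 1 PR+/- Dnmt3a-/- array, and at least 6.73 in the other 10 arrays.

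Dnmt3a RNA was lower in every array labelled Dnmt3a-/-. Its log2 level was 7.46 ± 0.21 (SD, n = 3) in wild-type CMP and 6.42 ± 0.06 (n = 3) in Dnmt3a-/- CMP, and 7.44 ± 0.12 (n = 4) and 6.13 ± 0.08 (n = 3) in the GMP. The change was -1.04 ± 0.14 (SE) in CMP (limma adjusted p = 0.00198) and -1.31 ± 0.13 in GMP (adjusted p = 3.87e-04). In the PR+/- background the level was 7.13 ± 0.09 (n = 2) with Dnmt3a and 6.09 ± 0.20 (n = 4) without, a difference of -1.05 ± 0.18. That difference did not pass the threshold in the fit of 6 arrays (adjusted p = 0.478) and passed it when all 19 arrays shared 1 fit (adjusted p = 0.00908). Of the 31 Dnmt3a probe sets, 13 were lower by more than 1 on the log2 scale in both CMP and GMP, and 16 were lower in all Dnmt3a-/- arrays of both. Which probe sets lie in the deleted part of the gene is not given in the sources used here.

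**Figure D1:**
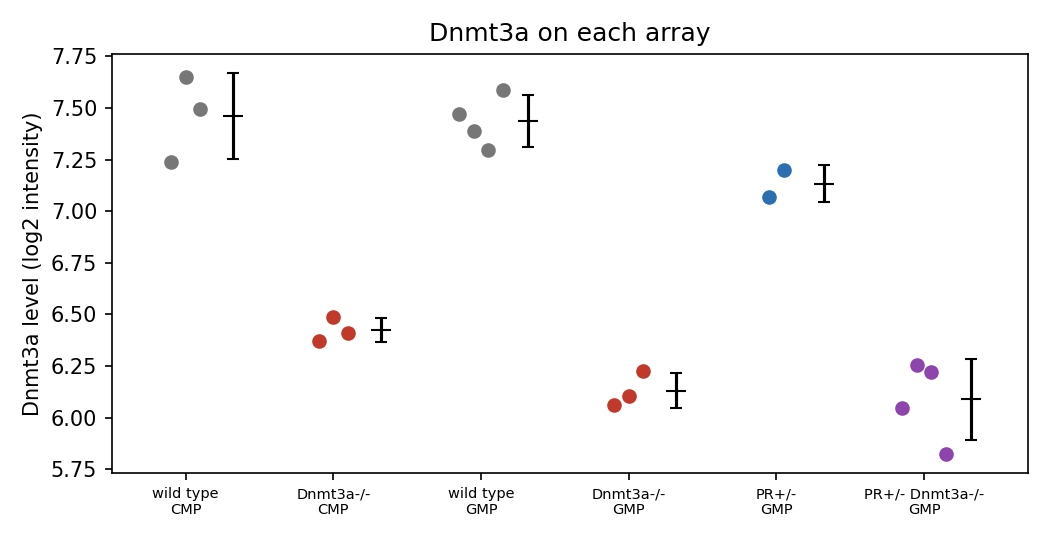
Dnmt3a level on each array (y axis, log2 intensity, not starting at 0) in the 6 groups (x axis), with points for arrays and the bar beside them for the mean and SD. The 10 arrays labelled Dnmt3a-/- lie between 5.83 and 6.49, all below the 9 arrays with Dnmt3a, which lie between 7.07 and 7.65.

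In CMP, loss of Dnmt3a came with higher RNA of the antigen presentation genes of MHC class II and with lower RNA of Csf1r and F13a1. H2-Eb1, a class II chain, rose by 3.40 ± 0.28 on the log2 scale (SE, 3 against 3 arrays; 10.5-fold), and Cd74, its chaperone, by 3.07 ± 0.29. Id2, a transcription regulator of dendritic and lymphoid cells, rose by 2.53 ± 0.20, the TGF-beta family ligand Gdf3 by 2.64 ± 0.26 and the double-stranded RNA sensor Tlr3 by 2.84 ± 0.33. Csf1r, the receptor for macrophage colony-stimulating factor, fell by 1.71 ± 0.18, and the transglutaminase subunit F13a1 of monocytes and platelets fell by 2.15 ± 0.25. Of 15781 genes, limma called 202, of which 145 were higher and 57 lower, and 2162 had an unadjusted p below 0.05. In all 202 the arrays of both genotypes did not overlap, as in 23.1% of all genes, where chance gives 10%.

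Platelet genes rose together in Dnmt3a-/- CMP. Of 16 measured megakaryocyte and platelet genes, 6 rose, 10 did not pass and none fell, and 15 rose adjusted over the list alone. Among them were the adhesion receptor Selp (1.86 ± 0.19), the clotting factor carrier Vwf (1.38 ± 0.20), the integrin Itga2b (1.38 ± 0.21) and the platelet receptor Clec1b (at least 1.70). The list had a median of 1.38 (camera adjusted p = 5.08e-22, adjusted p = 0.0116 with an estimated correlation). Of 15 dendritic cell genes, 6 rose and none fell, 9 of them adjusted over the list alone, and 4 of the 6 encode class II chains or Cd74. Their median was 0.75 (camera adjusted p = 5.64e-14, adjusted p = 0.0116 with an estimated correlation). The calls of H2-Aa (2.85 ± 0.56) and Batf3 (1.47 ± 0.29) were each lost in 5 of 6 fits without 1 array (adjusted p up to 0.136 and 0.130).

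Secondary granule genes were on the higher side in Dnmt3a-/- CMP and primary granule genes on the lower side, a difference between the lists that was not itself tested. Of 20 secondary granule and neutrophil maturation genes 5 rose and none fell, with 17 adjusted over the list alone and a median of 1.16 (camera adjusted p = 3.27e-14, adjusted p = 0.177 with an estimated correlation). The mean level of this list was 10.28 in Dnmt3a-/- replicate 1 and 8.87 and 8.82 in replicates 2 and 3, against 7.92 to 8.43 in wild type, and without replicate 1 the median was 0.73. The chitinase-like gene Chil3 rose by 2.17 ± 0.40, a call that was lost without wild-type replicate 1 (adjusted p = 0.0510) or 2 (adjusted p = 0.0826). Of 13 members of the primary granule list 4 fell and none rose, 5 adjusted over the list alone. Among them were the peroxidase Mpo (-0.86 ± 0.13) and Alas1 (-1.57 ± 0.25), an enzyme of haem synthesis rather than a granule protein. The calls of Prtn3 (-1.54 ± 0.29) and Ctsg (-1.19 ± 0.25) were each lost in 5 of 6 fits without 1 array (adjusted p up to 0.110 and 0.140). That list had a median of -0.58 (camera adjusted p = 1.41e-04, adjusted p = 0.312 with an estimated correlation). Its mean level was 8.95 in wild-type replicate 1, no higher than in the Dnmt3a-/- arrays (8.95 to 9.22), and 9.98 and 9.97 in wild-type replicates 2 and 3. The mean change of -0.59 was -0.93 without wild-type replicate 1, and the median was -0.34 without wild-type replicate 3.

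Of 20 monocyte and macrophage genes 3 fell (Csf1r, F13a1 and Ly86, a partner of a Toll-like receptor homologue) and 1 rose, the galectin Lgals3 (1.57 ± 0.20), while the list as a whole was not called (median -0.07; camera adjusted p = 0.735). The call of Ly86 was lost without any 1 of the 6 arrays (adjusted p between 0.0527 and 0.0972). Of 13 B cell genes 2 rose, the surface antigen Ms4a1 (at least 1.40) and Cd22 (0.90 ± 0.19). The call of Cd22 was lost in 4 of the 6 fits without 1 array (adjusted p up to 0.162). Of 25 stem and multipotent progenitor genes 4 rose and none fell. In such fits Mllt3 lost its call 5 times, Tek 4 times, and Mecom and Hlf 2 times each (adjusted p up to 0.108). The stem list, 9 up and 1 down adjusted over the list alone, had camera adjusted p = 5.80e-06 (adjusted p = 0.125 with an estimated correlation). No member of the cell cycle list passed over all genes, 6 of 28 fell adjusted over the list alone, and camera placed the list lower (median -0.30; adjusted p = 8.39e-06, adjusted p = 0.177 with an estimated correlation). Erythroid (median 0.30), mitochondrial respiration (0.04) and ribosomal protein genes (0.22) were higher by camera with no member past the threshold (adjusted p = 0.0389, adjusted p = 0.0145 and adjusted p = 0.00811). None of these calls held with an estimated correlation (adjusted p = 0.595, adjusted p = 0.312 and adjusted p = 0.312). The erythroid call was lost without wild-type replicate 2 or 3 or Dnmt3a-/- replicate 1 (adjusted p = 0.346, adjusted p = 0.715 and adjusted p = 0.0727), and the mitochondrial call without wild-type replicate 3 (adjusted p = 0.0650).

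The count in CMP depended on single arrays, on the processing and on the Y-linked signal, which was low in all 3 Dnmt3a-/- arrays and in 1 of 3 wild-type arrays. It was 93 and 87 without wild-type replicate 2 or 3, 103, 94 and 61 without Dnmt3a-/- replicate 1, 2 or 3, and 450 without the 3 wild-type arrays of lowest correlation. It was 1064 with array weights, 95 with the median of a gene's probe sets and 100 with only these 2 groups fitted. With that median Vwf (1.08), Mpo (-0.73), Alas1 (-1.35) and Ly86 (-0.93) did not pass (adjusted p between 0.0523 and 0.0840), and with only 2 groups these 4 and Chil3 did not (adjusted p between 0.0577 and 0.119). Chil3 was also lost with all 19 arrays in 1 fit (adjusted p = 0.140), and Ms4a1 (adjusted p = 0.0809) and Ly86 (adjusted p = 0.0980) with the brighter probe sets. With the Y-linked signal as a covariate 79 genes passed, 64 of them among the 202. All 202 kept their sign, with a median ratio of effect sizes of 1.02 and of standard errors of 1.23. Of the genes named above, H2-Aa, Batf3, Mecom, Hlf, Tek, Ctsg, Cd22, Ly86 and Chil3 did not pass with it (adjusted p between 0.0641 and 0.147). With only arrays of low Y-linked signal 75 genes passed, where the lone wild-type CMP array is assumed to vary like the other groups. In that fit Tlr3, Vwf, Itga2b, Clec1b, Mpo, Ms4a1, Ly86 and Chil3 did not pass (adjusted p between 0.0861 and 0.295).

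In GMP, the class II genes were again higher without Dnmt3a, together with the mast cell and basophil receptor Fcer1a. H2-Aa rose by 3.67 ± 0.53 (SE, 3 against 4 arrays; 12.7-fold), H2-Eb1 by 3.20 ± 0.26, Cd74 by 2.82 ± 0.27 and H2-Ab1 by 2.19 ± 0.30. With the median of a gene's probe sets H2-Ab1 (1.43; adjusted p = 0.134) and H2-Aa (3.49; adjusted p = 0.0524) did not pass. Fcer1a, the binding chain of the receptor for IgE, rose by 3.47 ± 0.43, Chil3 by 3.04 ± 0.38, Gdf3 by 2.95 ± 0.24, Id2 by 1.69 ± 0.19 and the surface antigen Thy1 by 1.44 ± 0.19. The growth factor gene Nrg1 fell by 2.10 ± 0.22, and Ly86 fell by 1.68 ± 0.19. Of 15781 genes, limma called 210, 142 higher and 68 lower, and 2986 had an unadjusted p below 0.05. In 209 of them the genotypes did not overlap, as in 16.6% of all genes, where chance gives 5.71%.

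Secondary granule genes were also on the higher side in Dnmt3a-/- GMP. All 20 had values above 0 and 5 rose, 16 adjusted over the list alone, with a median of 1.17 (camera adjusted p = 2.49e-15, adjusted p = 0.242 with an estimated correlation), or of 0.72 without Dnmt3a-/- replicate 1. The antimicrobial peptide gene Camp rose by 1.70 ± 0.32, a call lost without wild-type replicate 4 (adjusted p = 0.0607) or Dnmt3a-/- replicate 1 (adjusted p = 0.131) or 3 (adjusted p = 0.0581). Of 16 basophil and mast cell genes 3 rose and none fell, and 7 rose and 1 fell adjusted over the list alone. They were Fcer1a, the IgE receptor chain Ms4a2 (2.28 ± 0.43) and the transcription factor Gata2 (1.12 ± 0.24). The list had camera adjusted p = 2.59e-04 (adjusted p = 0.352 with an estimated correlation). The calls of Ms4a2 and Gata2 were lost without wild-type replicate 1 or 4 or Dnmt3a-/- replicate 1 or 2, and that of Gata2 also without wild-type replicate 3 (adjusted p between 0.0593 and 0.194).

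Of 16 megakaryocyte and platelet genes 3 rose in GMP, 7 adjusted over the list alone, and none fell. They were Selp (1.06 ± 0.18), Itga2b (1.11 ± 0.19) and the tetraspanin Cd9 (1.18 ± 0.22), and each call was lost without Dnmt3a-/- replicate 1 or 2 (adjusted p between 0.0526 and 0.103). The list had camera adjusted p = 4.14e-08 (adjusted p = 0.242 with an estimated correlation). Of 15 dendritic cell genes, 4 rose, all of them class II chains or Cd74, 5 adjusted over the list alone (camera adjusted p = 9.18e-04, adjusted p = 0.269 with an estimated correlation). Of 20 monocyte genes 3 fell, Ly86, Csf1r (-0.87 ± 0.17) and the transcription factor Irf8 (-1.18 ± 0.24). The Csf1r call was lost without wild-type replicate 1 or any 1 Dnmt3a-/- replicate (adjusted p between 0.0681 and 0.116). That of Irf8 was lost without any array but wild-type replicate 2 (adjusted p between 0.0608 and 0.145).

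Camera also placed the erythroid, stem, eosinophil, mitochondrial respiration and ribosomal protein lists higher in Dnmt3a-/- GMP. Over all genes 1 of 17 erythroid, 2 of 25 stem, 0 of 6 eosinophil, 1 of 22 mitochondrial and 0 of 12 ribosomal members rose, and none fell. Their camera values were adjusted p = 0.00995, adjusted p = 0.0159, adjusted p = 0.00335, adjusted p = 1.51e-04 and adjusted p = 0.00335. With an estimated correlation they were adjusted p = 0.646, adjusted p = 0.371, adjusted p = 0.368, adjusted p = 0.242 and adjusted p = 0.352. The erythroid call was lost without wild-type replicate 3 or Dnmt3a-/- replicate 1, and the stem call without wild-type replicate 3 or Dnmt3a-/- replicate 1 or 2 (adjusted p between 0.0502 and 0.139). The mean level of the eosinophil list was 5.89 and 5.55 in wild-type replicates 1 and 2, the arrays with high immediate early genes. It was 7.21 and 7.24 in wild-type replicates 3 and 4, near the 7.24 to 7.54 of the Dnmt3a-/- arrays.

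The count in GMP was 128 and 103 without wild-type replicate 1 or 4, and 49 and 80 without Dnmt3a-/- replicate 1 or 2. It was 1734 with array weights, 99 with the median of a gene's probe sets, 135 with the brighter probe sets and 75 with only these 2 groups fitted. With that median Selp, Itga2b, Cd9 (0.68), Csf1r, Ms4a2 and Gata2 did not pass either (adjusted p between 0.0627 and 0.262). With only 2 groups Itga2b, Cd9, Csf1r, Irf8 and Gata2 did not (adjusted p between 0.0564 and 0.115), and with all 19 arrays in 1 fit Camp (adjusted p = 0.129) and Irf8 (adjusted p = 0.103) did not. The Y-linked signal was low in all 3 Dnmt3a-/- arrays and in 1 of 4 wild-type arrays, and with it as a covariate 68 genes passed, 53 of them among the 210. All 210 kept their sign, with a median ratio of effect sizes of 1.03 and of standard errors of 1.32. Selp, Itga2b, Cd9, Csf1r, Irf8, Camp, Ms4a2 and Gata2 did not pass with the covariate (adjusted p between 0.0535 and 0.146). With only arrays of low Y-linked signal 34 genes passed, where the lone wild-type GMP array is assumed to vary like the other groups. These 8 genes again did not pass, nor did H2-Ab1, Fcer1a, Id2, Chil3 and Ly86 (adjusted p between 0.0829 and 0.287).

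Averaged over both cell types, 907 genes differed between the genotypes, 558 higher and 349 lower without Dnmt3a. H2-Eb1 (3.30 ± 0.19), Cd74 (2.94 ± 0.20), Gdf3 (2.79 ± 0.18), Chil3 (2.60 ± 0.28), Id2 (2.11 ± 0.14) and Selp (1.46 ± 0.13) rose. F13a1 (-1.48 ± 0.17), Ly86 (-1.35 ± 0.14) and Csf1r (-1.29 ± 0.12) fell, as did the interferon-induced GTPase Gbp3 (-1.05 ± 0.10). By limma, 3771 genes had an unadjusted p below 0.05. The fit treats all arrays as separate mice, although adjacent title numbers in Dnmt3a-/- may mark CMP and GMP of 1 mouse; with these as pairs 591 genes passed, all among the 907. Array weights gave 3248, the median of a gene's probe sets 493 and a minimum of 1.5-fold 455. With the Y-linked signal as a covariate 161 genes passed, 132 of them among the 907, with a median ratio of standard errors of 1.49. The count was 592 and 486 without wild-type CMP replicate 2 or 3, 439, 471 and 452 without Dnmt3a-/- CMP replicate 1, 2 or 3, and 371 and 519 without Dnmt3a-/- GMP replicate 1 or 2. Without the CMP and GMP arrays of an adjacent pair together it was 214, 285 and 457 for replicates 1, 2 and 3.

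Camera placed 8 lists higher in the averaged contrast, and with all arrays the megakaryocyte list alone held with an estimated correlation. Of 16 megakaryocyte and platelet genes 12 rose (15 adjusted over the list alone; median 1.10; camera adjusted p = 9.81e-18, adjusted p = 0.0288 with an estimated correlation), and of 20 secondary granule genes 14 rose (17 adjusted over the list alone; median 1.15; adjusted p = 9.81e-18, adjusted p = 0.138 with an estimated correlation). The highest arrays of the secondary granule list, Dnmt3a-/- CMP and GMP replicate 1 (10.28 and 10.32), carry adjacent title numbers and may come from 1 mouse. Without both, 7 of the 20 rose, with a median of 0.71 (camera adjusted p = 2.99e-19, adjusted p = 0.0122 with an estimated correlation). Without Dnmt3a-/- CMP and GMP replicate 2 the megakaryocyte list did not hold with an estimated correlation (adjusted p = 0.0587). Of 15 dendritic cell genes 8 rose (8 adjusted over the list alone; median 0.43; adjusted p = 6.16e-09, adjusted p = 0.0504 with an estimated correlation). Of 25 stem genes 7 rose and 1 fell (10 and 2 adjusted over the list alone; median 0.29; adjusted p = 3.98e-05, adjusted p = 0.138 with an estimated correlation). Of 16 basophil and mast cell genes 4 rose and 1 fell (7 and 1; median 0.41; adjusted p = 0.00112, adjusted p = 0.422 with an estimated correlation). Of 17 erythroid genes 3 rose (4; median 0.23; adjusted p = 0.00529, adjusted p = 0.521 with an estimated correlation), a call lost without wild-type CMP replicate 3 (adjusted p = 0.0699). Of 22 mitochondrial respiration genes 4 rose (8; median 0.14; adjusted p = 2.83e-04, adjusted p = 0.175 with an estimated correlation), and of 12 ribosomal protein genes none passed over all genes and 4 rose adjusted over the list alone (median 0.24; adjusted p = 7.68e-04, adjusted p = 0.240 with an estimated correlation).

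The cell cycle list was the only one that camera placed lower in the averaged contrast with all arrays, a call lost without wild-type CMP replicate 1 (adjusted p = 0.0909) or wild-type GMP replicate 3 (adjusted p = 0.0809). Of its 28 members 3 fell, also 3 adjusted over the list alone (median -0.17; adjusted p = 0.0138, adjusted p = 0.516 with an estimated correlation). Camera called none of the remaining lists with all arrays. It called the B cell list without wild-type CMP replicate 1 or Dnmt3a-/- CMP replicate 3 (up; adjusted p = 3.78e-04 and adjusted p = 0.0362), the primary granule list without wild-type CMP replicate 1 or Dnmt3a-/- CMP replicate 1 (down; adjusted p = 2.36e-04 and adjusted p = 0.0480) and the interferon list without Dnmt3a-/- GMP replicate 3 (up; adjusted p = 0.0353). Without adjacent pairs it called the primary granule list (replicates 1; down; adjusted p = 0.0334), and the B cell and interferon lists (replicates 3; up; adjusted p = 0.0182 and adjusted p = 0.0122). Of 20 monocyte and macrophage genes 2 rose and 4 fell (3 and 6 adjusted over the list alone; adjusted p = 0.571). Of 13 primary granule genes 1 rose and 3 fell (1 and 5; adjusted p = 0.132), and of 24 interferon-stimulated genes 3 rose and 1 fell (4 and 2; adjusted p = 0.171). Of 13 B cell genes 2 rose (2; adjusted p = 0.146), of 16 T and NK cell genes 1 rose (1; adjusted p = 0.560) and of 20 p53 target genes 1 rose (1; adjusted p = 0.924). The medians of the T and NK cell and p53 target lists were -0.08 and -0.03 where camera pointed up. Of 18 immediate early and heat shock genes 1 fell (1; adjusted p = 0.678) and of 21 imprinted genes 1 fell (1; adjusted p = 0.318). None of 6 eosinophil (0; adjusted p = 0.521), 19 retinoic acid pathway (0; adjusted p = 0.678) and 20 germline genes passed, although 1 germline gene rose and 4 fell adjusted over the list alone (adjusted p = 0.262). Of the 20 germline genes 0 lay above the median gene in wild-type CMP or GMP. Their median level is the one taken as background, so members at or under it cannot show a fall. Among the lists counted without a test, 5 of 24 myeloid transcription factor genes rose and 2 fell (5 and 4 adjusted over the list alone). Dnmt3a alone of 15 DNA methylation machinery genes fell (1 rose and 1 fell adjusted over the list alone), 1 of 6 sort marker genes fell (1), and both measured sex-linked genes, Eif2s3y and Kdm5d, were lower (2).

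**Figure D2:**
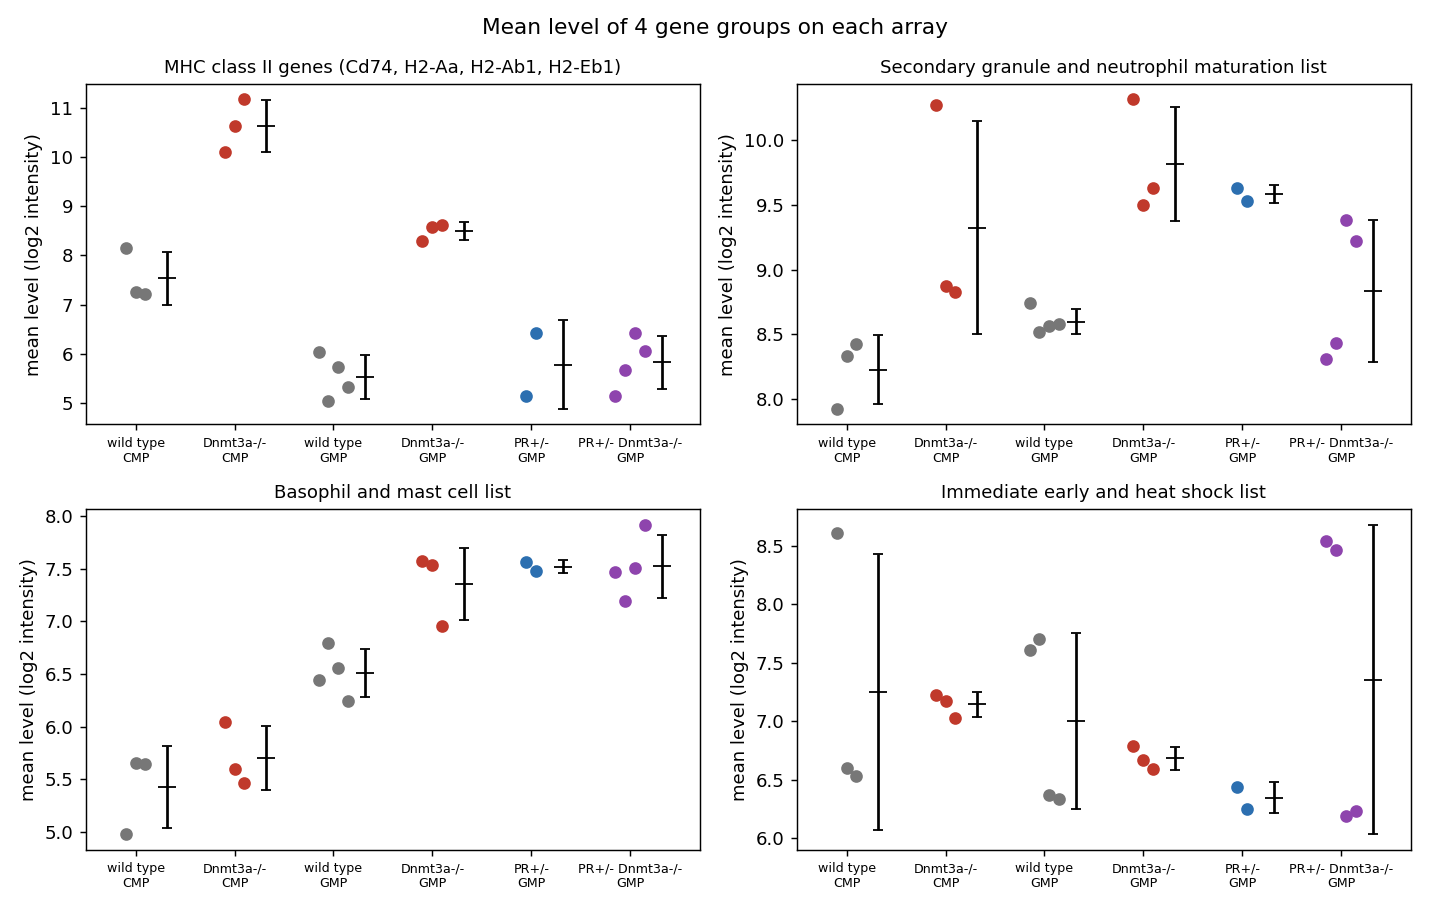
Mean level of 4 gene groups on each array (y axes, log2 intensity, not starting at 0) by group (x axes), with points for arrays and bars for the mean and SD beside them. The class II genes average 10.6 in Dnmt3a-/- CMP against 7.54 in wild type and 8.50 in Dnmt3a-/- GMP against 5.53, while the immediate early genes stand high in single arrays of 3 groups.

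Genes called in both CMP and GMP moved in the same direction after Dnmt3a loss. The log2 changes correlated across 15781 genes with r = 0.471, where genes are not independent replicates, nor are CMP and GMP arrays if they share a mouse. Both cell types called 43 genes higher, where 1.3 are expected if calls are independent, and 9 lower, where 0.246 are expected, and none in opposite directions. Both contrasts come from 1 fit that shares the spread of each gene. In both, title numbers and in large part the Y-linked signal follow genotype. Calls may therefore be shared for reasons other than Dnmt3a, which was not tested. Of the 202 genes called in CMP 177 (87.6%) had the same sign in GMP. The test of the difference itself, by limma, called 0 of 15781 genes, with 1083 at an unadjusted p below 0.05. On simulated data this test recovered 37% of 2-fold and 91% of 4-fold differences, so 0 does not show that the effects are alike. Large changes in 1 cell type were small in the other for some genes, such as F13a1 (-2.15 in CMP and -0.80 in GMP), Irf8 (-0.07 and -1.18) and Alas1 (-1.57 and 0.28), chosen after their values were seen (adjusted p of the difference between 0.182 and 0.518). The test called 48 with array weights and 10 without the 3 wild-type arrays of lowest correlation.

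The nearest genes were Nrg4 and Kcnip3, whose difference of GMP minus CMP effect was 1.97 ± 0.29 (adjusted p = 0.0856) and 1.51 ± 0.24 (adjusted p = 0.122). Alas1 (1.86 ± 0.34) and Mpo (0.95 ± 0.18), which fell in CMP, followed (both adjusted p = 0.182), and Shtn1 was at -1.89 ± 0.31 (adjusted p = 0.166). Without wild-type CMP replicate 1 the count was 23, with Alas1 (adjusted p = 0.00130), Mpo (adjusted p = 0.0328), Nrg4 and Kcnip3 past the threshold, and it was 1 without wild-type CMP replicate 3 or wild-type GMP replicate 2. By camera the primary granule list was higher in GMP relative to CMP (median 0.56; adjusted p = 5.02e-07), as were the eosinophil (1.34; adjusted p = 1.09e-05), cell cycle (0.31; adjusted p = 1.09e-05) and basophil lists (0.36; adjusted p = 0.0126). The megakaryocyte (-0.69; adjusted p = 1.09e-05) and dendritic lists (-0.49; adjusted p = 2.92e-04) were lower. With an estimated correlation none was called, at adjusted p = 0.644 for the basophil list and adjusted p = 0.205 for the others.

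Wild-type GMP differed from wild-type CMP as their positions in the myeloid lineage describe. The eosinophil granule genes Prg2 (4.47 ± 0.70, SE, 4 against 3 arrays), Ear6 (at least 3.51), Prg3 (3.29 ± 0.41) and Epx (2.75 ± 0.43) rose, and so did the basophil proteases Prss34 (4.11 ± 0.48) and Mcpt8 (2.60 ± 0.35). Dntt, the lymphoid DNA polymerase, fell by 4.09 ± 0.41, the receptor tyrosine kinase Flt3 fell by 2.83 ± 0.21, the water channel Aqp1 fell by 3.23 ± 0.38 and the erythroid transcription factor Gata1 fell by 2.38 ± 0.24. Of 15781 genes, limma called 678, 295 higher and 383 lower in GMP, and 2565 had an unadjusted p below 0.05. The cell types did not overlap in 671 of them, as in 13.9% of all genes, where chance gives 5.71%. Dnmt3a itself was -0.03 ± 0.13 (adjusted p = 0.952), and its relative Dnmt3b was lower (-0.60 ± 0.13), a call lost without wild-type CMP replicate 2 (adjusted p = 0.0599) or 3 (adjusted p = 0.0662).

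Of 17 erythroid genes 11 fell and none rose from CMP to GMP (14 adjusted over the list alone), among them Klf1 (-2.43 ± 0.40). Of 16 megakaryocyte and platelet genes 10 fell (13), among them Gp5 (-2.41 ± 0.45), of 25 stem genes 12 fell (17), among them Meis1 (-2.02 ± 0.31) and Slamf1 (lower by at least 1.35), and of 15 dendritic genes 9 fell (9), among them Clec9a (-2.62 ± 0.35). These 4 lists were called by camera (adjusted p = 1.25e-22, adjusted p = 7.09e-15, adjusted p = 3.50e-18 and adjusted p = 1.11e-11) and with an estimated correlation (adjusted p = 0.0189, adjusted p = 0.0178, adjusted p = 0.0103 and adjusted p = 0.0178). Of 13 primary granule genes 5 rose (13), among them the protease Ctsc (1.36 ± 0.16; camera adjusted p = 5.85e-12, adjusted p = 0.0742 with an estimated correlation). Of 16 basophil genes 8 rose and 1 fell (10 and 1; adjusted p = 2.83e-07, adjusted p = 0.116 with an estimated correlation). Camera also placed the eosinophil (4 of 6 rose; adjusted p = 1.25e-04), monocyte (3 of 20 rose; adjusted p = 0.00492), mitochondrial (0 of 22; adjusted p = 0.00626) and secondary granule lists (2 of 20 rose; adjusted p = 0.0354) higher. It placed the B cell (1 of 13 fell; adjusted p = 9.39e-05) and interferon lists (1 of 24 rose and 1 fell; adjusted p = 0.00472) lower. With an estimated correlation these 6 were not called (adjusted p between 0.116 and 0.64). The B cell list had a mean level of 6.52 in wild-type CMP replicate 1, 5.03 and 5.14 in replicates 2 and 3, and 4.64 to 5.03 in wild-type GMP. The secondary granule list stood at 7.92 in wild-type CMP replicate 1, 8.33 and 8.43 in replicates 2 and 3, and 8.52 to 8.74 in wild-type GMP. The low primary granule level of wild-type CMP replicate 1, given above, enters the change of that list here as well. Of the sort markers, the Fc receptor Fcgr3, which separates GMP from CMP, rose by 2.14 ± 0.45, and the stem cell factor receptor Kit fell by 0.63 ± 0.11. Fcgr3 missed the threshold without wild-type GMP replicate 3 (adjusted p = 0.0503) and Kit without the 3 wild-type arrays of lowest correlation (adjusted p = 0.0524).

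The wild-type arrays carry title numbers from 21986 to 21988 and from 22003 to 22012, and both sets hold CMP and GMP. The count was 658 within the first, which holds the 3 wild-type arrays of lowest correlation, 379 within the second and 1049 with the sets as a block, where the lone CMP array of the first set is assumed to vary like the other groups. Meis1 (adjusted p = 0.119) and Slamf1 (adjusted p = 0.109) did not pass within the first set. The count was 354 without wild-type CMP replicate 1, 380 with the median of a gene's probe sets and 258 with only these 2 groups fitted. With only 2 groups Ear6, Gp5, Fcgr3, Kit and Dnmt3b did not pass (adjusted p between 0.0516 and 0.110). Dnmt3b was also lost with the brighter probe sets and with the median (adjusted p = 0.105 and adjusted p = 0.246), and Slamf1 with the brighter ones (adjusted p = 0.0670).

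Dnmt3a-/- GMP differed from Dnmt3a-/- CMP in 1590 genes, 868 higher and 722 lower, with 3306 at an unadjusted p below 0.05 by limma. Prg2 (5.91 ± 0.75, SE, 3 against 3 arrays), Prg3 (5.32 ± 0.44), Fcer1a (4.66 ± 0.46), Prss34 (4.54 ± 0.51) and Mcpt8 (3.78 ± 0.38) rose. The neutrophil proteases Prtn3 (2.72 ± 0.29) and Ctsg (2.31 ± 0.25), Mpo (1.3 ± 0.13) and the granulocyte transcription factors Cebpe (3.34 ± 0.64) and Gfi1 (2.40 ± 0.22) rose as well. Dntt (-4.15 ± 0.44), Clec9a (-2.90 ± 0.37), Slamf1 (by at least 2.14), Flt3 (-2.15 ± 0.23) and Vwf (-2.01 ± 0.20) fell. Adjacent title numbers in Dnmt3a-/- as pairs gave 2060. In 1589 of the 1590 genes the cell types did not overlap, as in 32.4% of all genes, where chance gives 10%.

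Of 13 primary granule genes 11 rose (13 adjusted over the list alone), of 6 eosinophil genes 5 rose (5) and of 16 basophil genes 10 rose and 1 fell (11 and 2) from CMP to GMP without Dnmt3a. Of 16 megakaryocyte genes 13 fell (16), of 25 stem genes 15 fell (17), of 15 dendritic genes 11 fell (14), and of 17 erythroid genes 12 fell and 1 rose (13 and 1). Of 20 p53 target genes 3 fell (3). Camera called these 8 lists, and 7 of them also with an estimated correlation (adjusted p between 0.00893 and 0.0469), while the basophil list was not (adjusted p = 0.0692). It called 6 more that were not called with an estimated correlation (adjusted p between 0.0679 and 0.564). These were the cell cycle (3 of 28 rose; camera adjusted p = 9.29e-06), mitochondrial (0 of 22; adjusted p = 3.53e-04) and secondary granule lists (5 of 20 rose; adjusted p = 0.0306) on the higher side. The B cell (2 of 13 fell; adjusted p = 4.07e-04), interferon (4 of 24 fell and 1 rose; adjusted p = 8.37e-04) and immediate early lists (0 of 18; adjusted p = 0.0490) were on the lower side. Both genotypes called 239 genes higher in GMP, where 16.2 are expected if calls are independent, and 302 lower, where 17.5 are expected, with 1 in opposite directions (r = 0.675 across genes). The calls are not fully independent, since both contrasts share the spread of each gene. The count was 1043 and 968 without Dnmt3a-/- CMP replicate 2 or 3, 997 with the median of a gene's probe sets and 3853 with array weights.

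No gene passed the threshold for loss of Dnmt3a in GMP of PR+/- mice, the comparison closest to the title of the series. On simulated data this design recovered 24% of 2-fold and 77% of 4-fold changes, so 0 does not show that nothing changed. Of 15781 genes limma called 0, with 1256 at an unadjusted p below 0.05, and arrays did not overlap in 20.6% of all genes, where chance gives 13.3% for 2 against 4. The genes of smallest p were Tfpi, an inhibitor of coagulation (2.28 ± 0.21, SE; adjusted p = 0.117), Dnah8 (1.38 ± 0.18; adjusted p = 0.427) and Mpzl1 (1.28 ± 0.17; adjusted p = 0.427) on the higher side. On the lower side were Dnmt3a, the matrix protein Fn1 (-1.09 ± 0.17), Klrb1f (-1.16 ± 0.20) and the proton channel Hvcn1 (-1.40 ± 0.24), all at adjusted p = 0.478. The class II genes that rose in Dnmt3a-/- GMP stood at -0.28 ± 0.38 for H2-Eb1 and 0.44 ± 0.42 for Cd74. The count was 1 with array weights or without the dimmest 50% of genes, 21 with all 19 arrays in 1 fit, and 22 with the shared replicate numbers as a block, a pairing that the labels do not state. That block leaves PR+/- Dnmt3a-/- replicates 3 and 4 out of the comparison. It then rests on replicates 1 and 2, the arrays with high immediate early genes.

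Secondary granule genes lay lower in PR+/- Dnmt3a-/- GMP than in PR+/- GMP. None of 20 passed over all genes or adjusted over the list alone, but none was above 0, with a median of -0.71 (camera adjusted p = 4.89e-07, adjusted p = 0.807 with an estimated correlation). The mean level was 8.31 and 8.43 in PR+/- Dnmt3a-/- replicates 1 and 2, the arrays with high immediate early genes, 9.38 and 9.23 in replicates 3 and 4, and 9.63 and 9.53 in PR+/-. Immediate early and heat shock genes were on the higher side (median 0.97; camera adjusted p = 9.57e-04, adjusted p = 0.807 with an estimated correlation), as were stem genes (0.14; adjusted p = 0.0423, adjusted p = 0.807 with an estimated correlation). Without PR+/- Dnmt3a-/- replicates 1 and 2 the secondary granule median shrank to -0.28 (adjusted p = 0.0286), the stem list lost its call (0.08; adjusted p = 0.456) and the immediate early list pointed down (-0.14; adjusted p = 0.557). The eosinophil (0.43; adjusted p = 6.08e-04) and erythroid lists (0.25; adjusted p = 0.00750) were then called higher.

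The Dnmt3a-/- effect differed between the PR+/- and the wild-type background for 5 genes, all with a lower value in PR+/-. H2-Eb1, which rose by 3.20 in Dnmt3a-/- GMP, stood at -0.28 in the PR+/- background (difference -3.47 ± 0.41; adjusted p = 0.00769). The calcium-binding gene S100a4 stood at 1.53 and -1.52 (difference -3.05 ± 0.39; adjusted p = 0.00976), and the leukotriene enzyme Alox5 at 1.64 and -0.66 (-2.31 ± 0.26; adjusted p = 0.00769). Prss34 stood at 1.90 and -1.01 (-2.91 ± 0.36; adjusted p = 0.00843), and Gdf3 at 2.95 and 0.91 (-2.04 ± 0.27; adjusted p = 0.0132). A shift between array runs that all arrays of a background share drops out of this difference. One between wild-type and Dnmt3a-/- arrays would not, and 0 of 6 Dnmt3a-/- arrays carry a title number within the wild-type range. In PR+/- GMP the levels of S100a4 (10.03 against 8.42 in wild-type GMP), Alox5 (7.29 against 5.91) and Gdf3 (6.69 against 5.06) were already higher. H2-Eb1 stood at 5.81 against 5.43, and Prss34 was lower (8.76 against 9.63). How far these levels set the smaller effects was not tested. By limma, 2209 genes had an unadjusted p below 0.05. The count was 8 with the median of a gene's probe sets, 10 and 19 without the dimmest 25% or 50% of genes, 25 with all 19 arrays in 1 fit, where Prss34 did not pass (adjusted p = 0.0804), and 40 with array weights. It was 1 without the 3 wild-type arrays of lowest correlation. It was 762 with the shared replicate numbers as a block, a pairing that the labels do not state. In that fit PR+/- Dnmt3a-/- replicates 3 and 4 share no number with PR+/- and drop out of the effect. Its PR+/- part then rests on replicates 1 and 2, the arrays with high immediate early genes.

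All 20 secondary granule genes had a lower Dnmt3a-/- effect in the PR+/- background, with a median of -1.80. None passed over all genes, and 20 passed adjusted over the list alone (camera adjusted p = 1.77e-18, adjusted p = 0.22 with an estimated correlation). The mean level of this list was 8.60 in wild-type GMP, 9.82 in Dnmt3a-/- GMP and already 9.58 in PR+/- GMP. Across genes the effects in GMP with and without PR+/- correlated with r = -0.110, and 114 of the 210 genes called in GMP (54.3%) had the same sign in PR+/-. That correlation turned to 0.104 without the 5 arrays of lowest correlation. Without the 3 wild-type arrays of lowest correlation the 5 genes kept their sign (-1.93 to -3.52) but each stood at adjusted p = 0.0598. S100a4 missed the threshold without PR+/- replicate 1 (adjusted p = 0.0921) and Prss34 without PR+/- replicate 2 (adjusted p = 0.0631). Gdf3 missed it without either PR+/- replicate or Dnmt3a-/- replicate 2 or 3 (adjusted p between 0.0517 and 0.109) and with the Y-linked signal as a covariate (-1.94 ± 0.29; adjusted p = 0.0598), where the other 4 genes passed (adjusted p between 0.0343 and 0.0494). The count was 14 without PR+/- Dnmt3a-/- replicate 3.

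**Figure D3:**
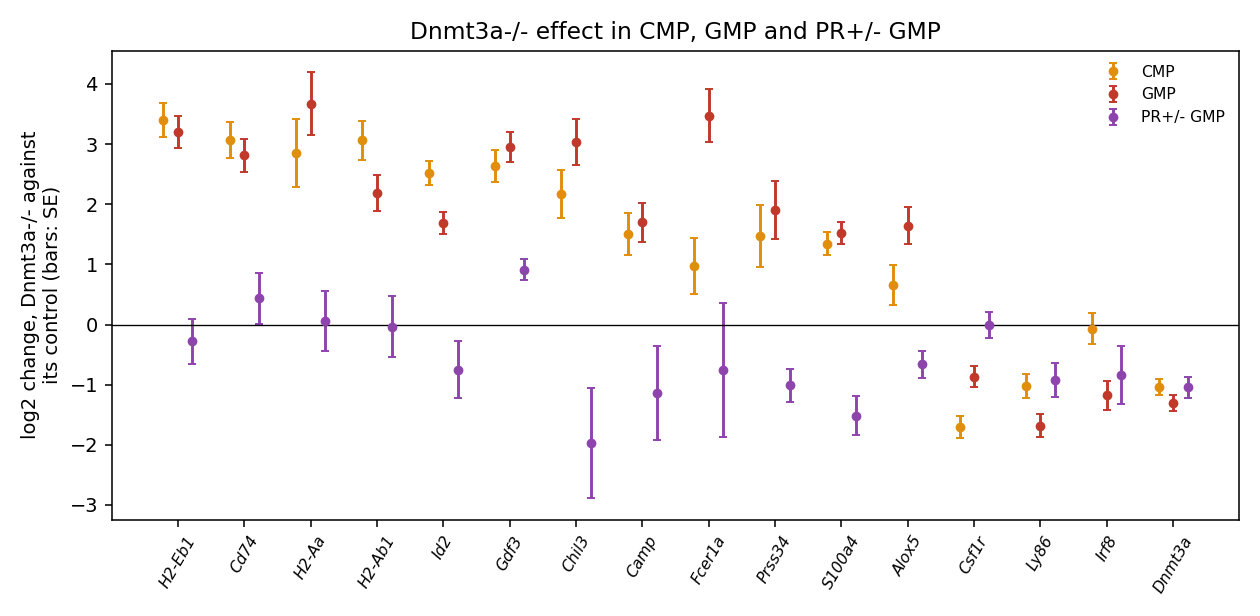
Change of 16 genes in Dnmt3a-/- samples against their controls (y axis, log2, bars for SE) in CMP, GMP and PR+/- GMP, with 1 point per gene and comparison (x axis, genes). H2-Eb1 stands at 3.40, 3.20 and -0.28 and Dnmt3a at -1.04, -1.31 and -1.05. Fcer1a in CMP lay near background, at 2.56 in wild type and 3.53 without Dnmt3a.

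PR+/- GMP differed from wild-type GMP in 484 genes, 345 higher and 139 lower, a difference that cannot be told apart from one between array runs. Thy1 (4.89 ± 0.37, SE, 2 against 4 arrays; 29.6-fold), the cell adhesion gene Cdh1 (4.54 ± 0.35), the membrane protein Perp (4.47 ± 0.39), the mast cell protease Cpa3 (3.70 ± 0.36) and the histamine enzyme Hdc (1.68 ± 0.18) rose. The Toll-like receptor homologue Cd180 (-2.92 ± 0.29), its partner Ly86 (-2.61 ± 0.25), Nrg1 (-2.18 ± 0.23) and Csf1r (-1.66 ± 0.19) fell. Dnmt3a stood at -0.30 ± 0.16 (adjusted p = 0.345). By limma, 2752 genes had an unadjusted p below 0.05, and groups did not overlap in all 484 called genes and in 28.5% of all genes, where chance gives 13.3%.

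Of 16 basophil and mast cell genes 7 rose and none fell in PR+/- GMP, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.83e-05, adjusted p = 0.291 with an estimated correlation). They included Cpa3, Hdc, Gata2 (2.26 ± 0.30) and Mcpt8 (1.86 ± 0.28). Of 20 secondary granule genes 2 rose, 6 adjusted over the list alone, and all 20 were above 0 (median 1.0; camera adjusted p = 2.09e-07, adjusted p = 0.506 with an estimated correlation). Of 20 monocyte genes 4 fell and 1 rose (5 and 1; camera adjusted p = 0.0781). Rxra, a retinoid receptor, was the 1 member of 19 on the retinoic acid pathway list that rose (1.57 ± 0.22; 2 adjusted over the list alone; list adjusted p = 0.975). The count was 43 without PR+/- replicate 1, where the lone PR+/- array is assumed to vary like the other groups, 284 without PR+/- replicate 2, 290 without wild-type replicate 4, and 218 without the 3 wild-type arrays of lowest correlation. It was 262 with the median of a gene's probe sets, 1045 with array weights and 850 with all 19 arrays in 1 fit. Gata2 (adjusted p = 0.0624), Mcpt8 (adjusted p = 0.0872) and Rxra (adjusted p = 0.0682) missed the threshold without PR+/- replicate 1.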

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

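The tests for B cells, for macrophages or monocytes, for the sex of the mice and for PR+/- alone were chosen after the result they measure had been seen at least in part, as were the fits without the arrays of lowest correlation and the splits that keep pairs of title numbers. The verdicts on dendritic cells and on macrophages or monocytes were changed after their values were seen.

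The higher RNA of MHC class II genes in Dnmt3a-/- CMP and GMP may come from other cells in the sorted samples, whose gates the labels do not give, or from the progenitors themselves, which was not tested. The median of 5 genes, Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ciita, was 2.94 with all arrays. It was 3.22 without the 3 wild-type arrays of lowest correlation and 3.22 with the Y-linked signal as a covariate. With that covariate 4 of the 5 passed, all but Ciita. For these 4 the values argue against array quality and sex as the whole cause. The mean level of Ciita was 4.57 in wild-type and 6.16 in Dnmt3a-/- CMP, but 4.34 and 4.50 in GMP. Dendritic cells stay open. The median of 11 list members outside class II was 0.118, below a bound set beforehand. However, Clec9a (1.35), Batf3 (0.74), Xcr1 (0.58) and Cd209a (0.43), 4 of the 11, rose. A median over the list cannot exclude cells that express only some of its members. Other dim members, Siglech (0.12), Irf4 (0.02), Zbtb46 (-0.04) and Ccr9 (0.02), stayed near 0, and Itgax stood at 0.28. The most abundant, Tcf4 (7.75 in wild-type CMP) and Runx2 (7.49), would hide a small share. Of 15 dendritic genes 8 lay above the median gene in wild-type CMP, but these include Cd74 and the class II chains to be explained, and 1 of the 15 is on another list. Monocytes or macrophages stay open for the same reason: of 20 genes 4 fell and 2 rose (median -0.0521), but 3 of the 4, Ly86 among them (9.97 in wild-type CMP), were abundant in wild type. B cells stay open too (median of 13 genes 0.0407, or 0.22 without wild-type CMP replicate 1, of which 2 rose and 7 lay above the median gene in wild-type CMP, with Cd79b, the most abundant, at 8.76 and 8.74 in CMP), and so does a run of arrays, since 0 of 6 Dnmt3a-/- arrays carry a title number within the wild-type range.

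The higher basophil and mast cell genes in PR+/- than in wild-type GMP (median 0.81) could reflect PR+/- or a difference between the arrays of both label styles. The larger of the medians of the ribosomal and mitochondrial lists was 0.116 of that median, which decides nothing, since the arrays were on a common scale as deposited and a shift of all genes alike could not appear. Of the other 19 tested lists, 2 had a median above 0.5 times that of the basophil list, so a shift shared by some lists stays open. No array of 1 label style holds the genotype of the other, so run and genotype cannot be told apart.

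The smaller Dnmt3a-/- effect in the PR+/- background may be a property of PR+/- cells or of these arrays. Over the 202 genes called in CMP, turned in the direction of their CMP change, the median Dnmt3a-/- effect was 0.455 in wild-type GMP. The effect in the PR+/- background came to 0.0850 of that with all arrays and to 0.106 without PR+/- Dnmt3a-/- replicates 1 and 2. For these genes that argues against noise of replicates 1 and 2 as the whole cause. It does not show a property of PR+/- cells. The genes were chosen in CMP, and there as in wild-type background GMP title numbers and in large part the Y-linked signal follow genotype. A shift with either could raise the 0.455 alone, which was not tested. It stays open whether PR+/- alone already moves these genes the same way, with a median of 0.115 against wild type and 64.9% of the genes in the same direction, since that contrast is bound to the label style.

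The effect of Dnmt3a loss differed between cell types for 6 lists by camera, with medians of GMP minus CMP of 0.36 for basophil and mast cell, 0.31 for cell cycle, 1.34 for eosinophil, 0.56 for primary granule, -0.49 for dendritic and -0.69 for megakaryocyte genes. It differed between the PR+/- and wild-type backgrounds for H2-Eb1 (-3.47), S100a4 (-3.05), Prss34 (-2.91), Alox5 (-2.31) and Gdf3 (-2.04). It also differed there by camera for 8 lists, with medians of -1.80 for secondary granule, -0.68 for basophil and mast cell, -0.57 for primary granule, -0.53 for megakaryocyte, -0.42 for mitochondrial respiration, -0.37 for ribosomal protein, -0.0581 for dendritic and 1.11 for immediate early genes. None of these 14 list calls held with an estimated correlation. Without PR+/- Dnmt3a-/- replicates 1 and 2 the medians between backgrounds were -0.17 for mitochondrial, -0.26 for primary granule, -0.39 for basophil and -0.23 for dendritic genes. The ribosomal (-0.21; adjusted p = 0.249) and immediate early calls (0.15; adjusted p = 0.724) were lost, and the immediate early list reversed without all 5 arrays of lowest correlation (-0.62; adjusted p = 0.00116).

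Single arrays stood apart from their group by Dixon's test for 5 of 129 values tested, where chance flags about 1 in 20, or 6.4. Ms4a2 was 6.50 in wild-type GMP replicate 3 and 5.47 to 5.63 in the others. Camp was 10.14 in wild-type GMP replicate 1 and 9.71 to 9.76 in the others. Adgre1 was 5.76 in wild-type GMP replicate 3 and 5.11 to 5.15 in the others. Nrg4 was 4.10 in wild-type GMP replicate 2 and 4.93 to 4.99 in the others. Cryab was 5.84 in PR+/- Dnmt3a-/- replicate 4 and 6.19 to 6.24 in the others.

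Few probe sets outside the gene comparisons passed in the averaged contrast, where 907 of 15781 genes did. They were tested singly, while a gene is a mean of its probe sets, so the shares are not alike in kind. Of 13469 probe sets with no gene symbol 16 passed the threshold, 12 higher and 4 lower without Dnmt3a, and of 1328 with several symbols 10 passed, 9 higher and 1 lower.

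Other splits of the same arrays tested whether chance could give the counts. In GMP the real split of wild type and Dnmt3a-/- gave 210 genes and was 1 of 35 with as many, with 41 at most in the others. Averaged over both cell types it gave 907 and was 1 of 100 drawn, with 11 at most in the others. GMP against CMP in wild type gave 678 and was 1 of 35, with 121 at most in the others. These shares are under 0.05, which argues against chance if the arrays are separate mice. Chance is not excluded, since 1 of 35 is the smallest share that 35 splits allow. Among the 95 averaged splits that keep adjacent Dnmt3a-/- title numbers on 1 side, the real one alone gave 907, with 427 at most in the others. In CMP (202 genes, 8 at most in the others, 1 of 10 splits) and for the cell types without Dnmt3a (1590 genes, 0 in the others, 1 of 10) the splits are too few for a share under 0.05. For the difference between the effects in CMP and GMP the real count was 0, so all 100 splits had to give as many, and this decides nothing. The highest of the others gave 110. It kept genotype in CMP, but in GMP it set the 3 Dnmt3a-/- arrays and wild-type replicate 4 against wild-type replicates 1 to 3. Genotype was thus nearly reversed in GMP, so an effect that both cell types share would add up in it. Whether that gave the 110 was not tested.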

How the results depend on the processing

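The fits without the arrays of lowest correlation, with title numbers, with adjacent Dnmt3a-/- numbers as pairs and with the Y-linked signal were chosen after seeing the data. Quantile normalisation, array centring, and eBayes with trend and robust settings kept each count of genes within 1.5 times its value and no centring or normalisation moved the median of all genes by over 0.1. Of the alternatives for single genes other than Dnmt3a, 3055 kept direction and side of the threshold, 361 lost the call, 25 gained it and 0 reversed; for lists 384 kept it, 114 lost it and 2 reversed. Signal over background limits dim genes: 10.1% of genes had means at or under the median germline level of 3.34 in all 6 groups, where no change can be measured.

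Counts are given in the order CMP, GMP, averaged, cell types in wild type, cell types in Dnmt3a-/-, difference between CMP and GMP, PR+/- Dnmt3a-/- against PR+/-, PR+/- against wild type, and difference between backgrounds, where those not named stayed within 1.5 times. Taking the median of a gene's probe sets gave 95, 99, 493, 380 and 997 in the first 5, 262 for PR+/- against wild type and 8 for the backgrounds. Array weights gave 1064, 1734 and 3248 in the first 3, 3853 for the cell types in Dnmt3a-/-, 48 for CMP and GMP, 1 in PR+/-, 1045 for PR+/- against wild type and 40 for the backgrounds. The brighter probe sets gave 135 in GMP. Fitting only the groups compared gave 100 in CMP, 75 in GMP and 258 for wild-type cell types, with fewer arrays behind the spread. A minimum of 1.5-fold gave 455 averaged. Removing the dimmest 25% gave 10 for the backgrounds, and removing 50% gave 19 there and 1 in PR+/-, with fewer genes tested. All 19 arrays in 1 fit gave 21 in PR+/-, 850 for PR+/- against wild type and 25 for the backgrounds. The replicate block gave 22 in PR+/- and 762 for the backgrounds, where PR+/- Dnmt3a-/- replicates 3 and 4 share no block with PR+/- and drop out of the effect. Without the 3 wild-type arrays the counts were 450 in CMP, 379 for wild-type cell types, 10 for CMP and GMP, 218 for PR+/- against wild type and 1 for the backgrounds. Title numbers as a block gave 1049 for wild-type cell types, and the arrays numbered 22003 to 22012 alone gave 379, the same split as without the 3 wild-type arrays, numbered 21986 to 21988. Adjacent Dnmt3a-/- numbers as pairs gave 591 averaged, kept every other count within 1.5 times and ended the calls of Aurka, Kif20a and Cdc6 among the genes named, and the list tests were not run with these pairs. Leaving out both arrays of a pair gave 214, 285 and 457 averaged. The Y-linked signal as a covariate gave 79, 68 and 161 in the first 3, and only arrays of low signal gave 75, 34 and 366. Apart from fewer genes or arrays, the cause was not tested.

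Leaving out each array in turn gave 61 to 211 genes in CMP, 49 to 262 in GMP, 371 to 1031 averaged, 354 to 710 for wild-type and 968 to 1176 for Dnmt3a-/- cell types. It gave 0 to 23 for CMP and GMP, 0 to 0 in PR+/-, 43 to 432 for PR+/- against wild type and 4 to 14 for the backgrounds. The correlation across genes of the effects in CMP and GMP was 0.408 to 0.480, and 0.552 without the dimmest 50% of genes. That of GMP with and without PR+/- was -0.175 to -0.0150 and reversed to 0.104 without the 5 arrays of lowest correlation; the cause was not tested.

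Of 72 list calls in 180 tests, 14 held with an estimated correlation, and fry made 44 calls, 40 of them shared; fry asks whether a list moves on balance, not whether it moves more than other genes. Without the 5 arrays the immediate early list reversed in PR+/- (signed -log10 p of -0.740) and in the difference between backgrounds (-3.76); the cause was not tested.

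With 1 array left out the Dnmt3a change was -1.15 to -0.94 in CMP, -1.35 to -1.25 in GMP, -1.23 to -1.13 averaged, -1.11 to -0.96 in PR+/- and -0.37 to -0.24 for PR+/- against wild type. The median of its probe sets taken singly was -0.80 in CMP and -0.95 in GMP, and the cause was not tested. In PR+/- it was -1.05 and past the threshold with all 19 arrays. Between wild-type cell types it was -0.14 to 0.0679 with 1 array left out, and reversed to 0.0679, 0.0210 and 0.19 (the last within arrays 21986 to 21988) without passing. Between Dnmt3a-/- cell types it passed with the brighter probe sets (-0.48) and with array weights (-0.31), and the cause was not tested.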

Other observations

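The genes named here belong to lists written beforehand, and the values are those of the averaged contrast of Dnmt3a-/- with wild type. The fits with the Y-linked signal as a covariate and with adjacent title numbers as pairs were chosen after seeing the data. Interferon-stimulated genes went both ways. Gbp3, an interferon-induced GTPase, fell by 1.05 ± 0.10, while Irf7, a transcription factor of the interferon response, rose by 0.71 ± 0.16 (adjusted p = 0.0243) and Ddx58, a sensor of viral RNA, rose by 0.73 ± 0.15 (adjusted p = 0.0172). With the Y-linked signal as a covariate Irf7 (0.93, adjusted p = 0.0808) and Ddx58 (0.79, adjusted p = 0.124) did not pass. With the median of a gene's probe sets Irf7 (0.45, adjusted p = 0.218) did not pass. Irf7 also missed the threshold without wild-type CMP replicate 3, Dnmt3a-/- CMP replicate 1 or 3, or Dnmt3a-/- GMP replicate 1 or 2 (adjusted p between 0.0510 and 0.0628), and Ddx58 without Dnmt3a-/- CMP replicate 1 (adjusted p = 0.0509) or Dnmt3a-/- GMP replicate 1 (adjusted p = 0.0559).

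Among cell cycle genes the mitotic kinase Aurka (-0.48 ± 0.12; adjusted p = 0.0411), the mitotic kinesin Kif20a (-0.39 ± 0.11; adjusted p = 0.0466) and the replication licensing factor Cdc6 (-0.33 ± 0.09; adjusted p = 0.0467) fell. With each of the 13 arrays left out in turn, Aurka missed the threshold 10 times (highest adjusted p = 0.102), Kif20a 12 times (highest adjusted p = 0.116) and Cdc6 11 times (highest adjusted p = 0.108). With the Y-linked signal as a covariate they stood at adjusted p = 0.291, adjusted p = 0.410 and adjusted p = 0.169, and with adjacent Dnmt3a-/- title numbers as pairs at adjusted p = 0.0563, adjusted p = 0.0616 and adjusted p = 0.0635. With the median of a gene's probe sets Aurka (-0.35, adjusted p = 0.396) and Cdc6 (-0.26, adjusted p = 0.378) did not pass, and with the brighter probe sets none of the 3 did (adjusted p between 0.0842 and 0.667).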
